A study of Mus musculus with 12 samples.

How the data were processed

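Cortex of C57BL/6 mice was profiled by RNA sequencing with 4 libraries each of WT, Het and KO animals at Mir137. Per the labels' protocols, TruSeq RNA v2 libraries were read as paired ends on a HiSeq 2000. The submitters' processing notes name CASAVA 1.4, TopHat2 2.0.13, Cuffdiff 2.2.1 and the mouse build mm9. Which tool did which step, and the gene annotation, are not given in the sources used here. Samples were grouped by the genotype in their titles.

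The authors deposited 3 pairwise tables of 23951 rows, each with an RPKM value per genotype per the file headers, so the libraries of a genotype are pooled into 1 value. The deposited tables also hold a p-value and a q-value per gene, per the file headers, and these come from the authors' own test. The q-values equal a Benjamini-Hochberg adjustment over genes with a p below 1, and a p of 1 was read as not tested. The smallest p is 5e-05. The deposited log2 fold column holds spreadsheet error cells and was not used. Per file, 27 gene names had turned into dates and 99 or 100 entries named several genes. No column was left without a genotype (0 unmapped). Both kinds stayed in the counts of genes called, and none of them is named. The plan written before the data were examined expected FPKM, and the headers say RPKM. The planned test for a table of 1 value per genotype applied unchanged. The same genotype's values differed between tables by a median of 0.0573% for WT, 0.680% for Het and 0.473% for KO, so tests were read only within a table.

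No test of gene expression was run here, since 1 value per genotype carries no spread: calls are the authors' q below 0.05. The depth per library is unknown, and pooled values show no whole reads from which it could be recovered. Log2 folds are differences of log2(RPKM + 1). A gene counted as measured with at least 1 RPKM in either genotype. For 41 gene lists covering brain regions, cell types, signalling families and cell states, calls were counted over all genes and adjusted over the list alone (Benjamini-Hochberg on the authors' p). The median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The list of 13 mitochondrially encoded genes was not analysed here. Genes named in the text follow a rule of 4 parts. They are Mir137, Mir137hg, Dpyd, Pde10a and published miR-137 targets of at least 1 RPKM; the 10 largest rises and 10 largest falls among called genes of at least 1 RPKM; up to 4 called members per list by smallest q; and the 10 genes called in the same direction in Het and KO with the largest mean fold. Mir137hg was not analysed here. The lists, the tests, the naming rule and the alternative settings were fixed before the data were examined.

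3' UTR sequences and transcript lengths came from GENCODE M21 on GRCm38, joined by gene name, which covered 94.0% of expressed genes for 3' UTRs and 99.3% for lengths in Het against WT. No coordinates are given, since this build differs from that of the tables. For each gene the longest annotated 3' UTR was searched for miR-137 sites, and medians were set beside 10000 random gene sets matched on expression and 3' UTR length. Overlap of calls and correlation of folds between Het and KO were compared with 100 simulations of unchanged genotypes that share the WT values.

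Alternatives covered pseudocounts of 0.1 and 0.01, a minimum of 5 RPKM, no minimum, a q threshold of 0.01, a minimum absolute log2 fold of 0.5, adjustment over the 3 comparisons together, recentred folds, the shortest 3' UTR and matching on base composition. They used 2000 random lists, or 1000 without a minimum. Matching on transcript length, in 10 bins each of expression and length, was added after seeing the data. So were runs of the site test without the genes of all lists, and of overlap and dose without striatal, choroid plexus and ribosomal list genes. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

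The steps were tested on simulated data for KO against WT over 13529 genes. Of 100 genes changed by a log2 fold of 0.5, 63% were called, and of 100 changed by 1, 100%. Calls on unchanged genes made up 6.86% of all calls. Of 100 unchanged lists of 20 genes 1 lay outside the range of 95% of random lists, and 100 of 100 lists raised by 0.3 lay above it. Simulated genes varied independently, so these runs cannot show how lists of genes that vary together behave. All 20 large gene sets raised by 0.05 lay above the range of their matched sets. Over 13589 genes a simulated covariance of 0.0375 was recovered as 0.0367, and a slope of 0.6 as 0.577.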

Results

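RNA was sequenced from the cortex of mice of 3 genotypes at Mir137, the gene of the brain-enriched microRNA miR-137: wild type (WT), heterozygous (Het) and knockout (KO). Each genotype had 4 libraries, 12 in all. The series asks what miR-137 does in neurodevelopment, and its title also names Pde10a, a phosphodiesterase that breaks down cyclic AMP and cyclic GMP and is abundant in striatal neurons. The values are the authors' RPKM, 1 per genotype in each of 3 pairwise tables, together with the authors' p and adjusted p for every gene tested. Because the libraries are pooled, no SD can be attached to a value, and the depth of the libraries is unknown. The titles number the libraries in pairs and the protocol speaks of duplicated samples. Nothing says that the 4 libraries of a genotype came from separate animals, so the p-values then measure only the spread between these libraries, which may be technical. A gene is said to rise or fall where its adjusted p in the authors' deposited table is below 0.05. Log2 folds are differences of log2(RPKM + 1), which understates the change of low genes.

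The targeted gene, Mir137, was listed at 0 in all 3 genotypes. Its precursor is far shorter than a messenger RNA, so this row checks none of the genotype labels. Dpyd, which lies close to Mir137 on the chromosome and encodes an enzyme of pyrimidine breakdown, stood in the authors' deposited table at 3.60 RPKM in WT and 2.92 in Het (adjusted p 0.318). The authors' deposited table of KO against WT gave Dpyd 3.16 RPKM in KO (adjusted p 0.492).

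Heterozygous cortex differed from WT most in genes of striatal projection neurons, which rose together, and in genes of the choroid plexus, the epithelium that secretes cerebrospinal fluid, which fell together. Adora2a, the adenosine receptor of indirect-pathway striatal neurons, rose 19.0-fold, from 1.17 to 22.2 RPKM, in the authors' deposited table. Ttr, the thyroid hormone carrier made by choroid plexus, fell from 2027 to 281 RPKM in the authors' deposited table, 7.21-fold lower. Genes of dividing progenitors, immature neurons and ribosomal proteins also rose, and glucocorticoid-responsive and inflammatory genes fell. Unless another value is given, each gene named for this comparison had an adjusted p of 0.00135, the smallest in the authors' deposited table. Of 14159 genes tested, 559 rose and 716 fell.

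Pde10a rose in Het from 12.7 to 35.2 RPKM in the authors' deposited table, 2.78-fold. Among 18 measured phosphodiesterases, 3 rose and 1 fell (3 and 2 adjusted over the list alone). The other members that rose in the authors' deposited table were Pde1b, a calmodulin-activated enzyme at 83.7 against 31.3 RPKM, and the cyclic AMP enzyme Pde7b at 7.97 against 3.46. Pde1a fell from 65.2 to 39.1 RPKM in the authors' deposited table.

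Of 23 measured striatal projection neuron markers, 21 rose (23 adjusted over the list alone). Their median log2 fold was 1.55, above all 10000 random lists matched on expression. The enkephalin precursor Penk rose 11.2-fold to 113 RPKM in the authors' deposited table. Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, went from 20.6 to 172 RPKM in the authors' deposited table. The dopamine receptor genes Drd1a and Drd2 reached 7.96 and 10.8 RPKM in the authors' deposited table, from 0.755 and 1.65. The sodium channel subunit Scn4b rose 8.83-fold, the retinoid receptor Rxrg 6.29-fold and the G-protein regulator Rgs9 5.50-fold in the authors' deposited table. Rmrp, an RNA component of a ribonuclease and a short transcript, rose from 3.91 to 21.8 RPKM (adjusted p 0.0303 in the authors' deposited table).

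Of 14 measured choroid plexus and ependymal markers, 10 fell (10 adjusted over the list alone), with a median log2 fold of -1.29, below all 10000 random lists. The folate receptor Folr1 fell from 13.5 to 3.09 RPKM and the water channel Aqp1 6.46-fold, from 7.73, in the authors' deposited table. Otx2, a homeobox gene of choroid plexus, fell from 3.91 to 0.634 RPKM in the authors' deposited table. Meningeal and fibroblast markers moved the same way, with 7 of 15 lower (7 adjusted over the list alone). They include the proteoglycan Dcn, which fell from 31.9 to 5.94 RPKM in the authors' deposited table. S100a9 and Lrg1, which neutrophils express, stood among the largest falls, though no list of neutrophil genes was tested: S100a9 went from 28.9 to 0.527 RPKM (adjusted p 0.00841 in the authors' deposited table). Lrg1 fell from 6.66 to 0.165 RPKM (adjusted p 0.00434 in the authors' deposited table).

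Neural progenitor and cell cycle genes rose, 13 of 21 measured (17 adjusted over the list alone), with a median log2 fold of 0.67. Top2a, the topoisomerase of dividing cells, went from 2.41 to 6.10 RPKM and the replication helicase gene Mcm5 from 1.97 to 4.53 in the authors' deposited table. Among 20 immature neuron genes 10 rose (13 adjusted over the list alone), led by Igfbpl1 at 36.9 against 20.6 RPKM in the authors' deposited table. Doublecortin (Dcx), a microtubule protein of migrating neurons, stood at 34.0 against 23.0 RPKM in the authors' deposited table. Ezh2, the histone methyltransferase of polycomb complex 2 and a published miR-137 target, rose from 4.52 to 7.66 RPKM in the authors' deposited table. It was 1 of 2 members that rose among 25 measured polycomb and chromatin regulators (2 higher and 1 lower adjusted over the list alone).

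Of 31 measured ribosomal protein genes, 15 rose (28 adjusted over the list alone), with a median log2 fold of 0.31. Rps28 stood at 721 against 498 RPKM in the authors' deposited table. Nuclear respiratory chain genes had a median of 0.19, and 3 of 29 rose (4 adjusted over the list alone). Ribosomal and respiratory genes had median transcript lengths of 1059 and 1661 nt. Expressed genes other than ribosomal protein genes were put in 10 length bins. In this comparison their median log2 fold went from 0.13 in the shortest bin to -0.10 in the longest.

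Glucocorticoid-responsive genes fell, 9 of 14 measured (9 adjusted over the list alone), with a median log2 fold of -0.50. The steroid receptor co-chaperone Fkbp5 went from 23.0 to 14.2 RPKM, the metallothionein Mt2 from 321 to 184 and the sulfotransferase Sult1a1 from 14.5 to 2.81 in the authors' deposited table. Interferon and inflammatory genes fell in 4 of 10 measured members (6 adjusted over the list alone), among them the class I histocompatibility gene H2-K1, at 9.68 against 20.4 RPKM in the authors' deposited table. Microglia markers were mixed, with 3 of 16 higher and 5 lower (3 and 6 adjusted over the list alone). The purinergic receptor P2ry12 rose to 41.1 from 20.7 RPKM, and the protease Ctss fell to 31.7 from 84.8, in the authors' deposited table.

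Glutamate receptor and postsynaptic genes fell in 9 of 33 members (11 adjusted over the list alone), with a median log2 fold of -0.20. The NMDA receptor subunits Grin2a and Grin2b stood at 5.66 and 5.60 RPKM against 9.32 and 9.60 in WT in the authors' deposited table. Presynaptic vesicle genes fell in 5 of 29 members (6 adjusted over the list alone), among them the scaffold gene Bsn at 14.7 against 21.3 RPKM in the authors' deposited table. Members of the glutamate receptor and presynaptic lists had median transcript lengths of 5887 and 4361 nt, where that of all genes expressed in KO or WT was 3392 nt. Against random lists matched on expression and transcript length, chosen after seeing the data, the medians of both lists stayed below the range of 95% of random lists. Under the same matching 3 lists that stood apart no longer did: hypothalamic markers at percentile 96.7, mature neuron genes at 3.05 and voltage-gated calcium channels at 5.10. Of those lists, 2 of 4 hypothalamic markers rose, 2 of 20 mature neuron genes fell and 4 of 18 calcium channel genes fell (2 higher and 1 lower, 2 lower and 4 lower adjusted over the list alone).

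Cortical layer markers changed in both directions. Among 14 deep-layer markers 7 rose and 4 fell (7 and 4 adjusted over the list alone): Foxp2, a transcription factor also present in striatum, rose 4.03-fold and the synaptotagmin Syt6 3.32-fold, and Sulf1 fell from 6.72 to 2.27 RPKM, in the authors' deposited table. Their median of 0.35 became -0.03 over members of at least 5 RPKM. Upper-layer markers rose in 4 of 12 members and fell in 3 (4 and 4 adjusted over the list alone). Oligodendrocyte precursor markers rose in 3 of 12 (6 adjusted over the list alone), including the receptor gene Gpr17 at 35.1 against 16.8 RPKM in the authors' deposited table. Immediate early genes rose in 9 of 24 and fell in 2 (11 and 3 adjusted over the list alone). The activity-regulated genes Arc and Npas4 reached 11.9 and 6.31 RPKM from 7.48 and 3.39 in the authors' deposited table.

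Other lists of this comparison held fewer calls. Thalamic markers fell in 4 of 9 members (2 higher and 4 lower adjusted over the list alone), including the transcription factor Tcf7l2 at 1.99 against 7.63 RPKM in the authors' deposited table. Of 14 endothelial markers 5 fell and 1 rose (6 and 2 adjusted over the list alone). Among 14 GABA receptor genes 3 fell and 1 rose (4 and 1 adjusted over the list alone), the latter being Gabrd at 14.5 against 6.54 RPKM in the authors' deposited table. Circadian genes fell in 3 of 16 members (1 higher and 4 lower adjusted over the list alone). Erythroid markers rose in 2 of 5 members (2 adjusted over the list alone), among them the globin gene Hbb-bt at 67.5 against 22.4 RPKM in the authors' deposited table. Over members with no minimum level the erythroid median was 0.00. In all, the medians of 26 lists lay outside the range of 95% of random lists. By construction 5% of random lists lie outside it. Genes of a cell type or pathway may vary together, and some lists share genes, so 5% is not the chance rate for these lists.

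**Figure D1:**
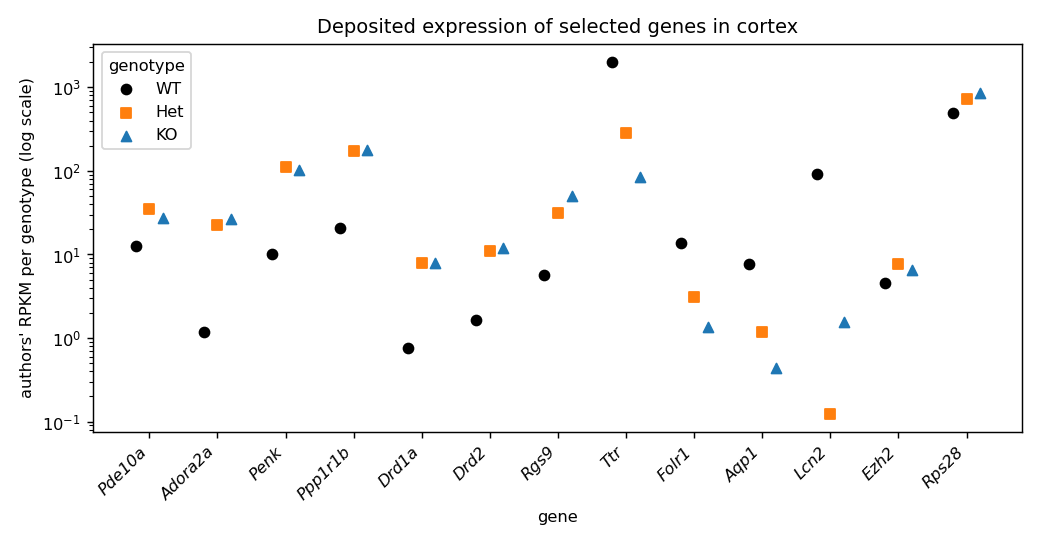
The authors' RPKM per genotype on a log scale for 13 genes, with 1 pooled value for each genotype and no error bars. Pde10a and the striatal genes from Adora2a to Rgs9 stand higher in Het and KO than in WT, and Ttr, Folr1 and Aqp1 stand lower.

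Knockout cortex differed from WT in many of the same groups. Striatal projection neuron genes rose and choroid plexus genes fell, ribosomal protein genes rose in 25 of 31 members, and immature neuron genes rose in 12 of 20. The authors' deposited table gave Adora2a 26.4 RPKM against 1.17, a 22.6-fold rise, and Ttr 83.6 against 2028, 24.3-fold lower. The lipocalin Lcn2, an acute-phase protein, fell 59.5-fold, from 91.7 to 1.54 RPKM, in the authors' deposited table. Each gene named for this comparison had an adjusted p of 0.000987, the smallest in the authors' deposited table, unless another value is given. Of 14059 genes tested, 945 rose and 1080 fell.

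Pde10a stood at 27.3 RPKM in KO against 12.7 in WT in the authors' deposited table, a 2.15-fold rise. Of 22 measured published miR-137 targets, 4 rose and 4 fell (4 and 7 adjusted over the list alone), and their median log2 fold of 0.00 lay at percentile 36.6 of random lists. Besides Pde10a, the authors' deposited table listed as higher the nuclear receptor Esrra at 23.5 against 14.4 RPKM, and Wbp1l at 17.8 against 12.3. Ezh2 rose from 4.52 to 6.60 RPKM (adjusted p 0.0130 in the authors' deposited table). The prostaglandin synthase Ptgs2 fell from 6.75 to 1.74 RPKM and Grin2a from 9.33 to 5.52 in the authors' deposited table. The vesicle fusion ATPase Nsf fell from 327 to 227 RPKM (adjusted p 0.00179 in the authors' deposited table). The ubiquitin ligase Mib1, which acts in Notch signalling, fell from 17.6 to 13.6 RPKM (adjusted p 0.0306 in the authors' deposited table). The synaptic targets Cplx1 and Gria1 had log2 folds of 0.00 and -0.29 (adjusted p 0.995 and 0.158 in the authors' deposited table). In Het, 2 of the 22 targets rose and 3 fell (3 and 6 adjusted over the list alone), with Csmd1, a complement-related synaptic gene, at 2.92 against 3.82 RPKM (adjusted p 0.0251 in the authors' deposited table).

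Of 23 measured striatal projection neuron markers 22 rose in KO (22 adjusted over the list alone), with a median log2 fold of 1.68. Penk rose 10.2-fold and Scn4b 9.91-fold in the authors' deposited table. Ppp1r1b reached 179 RPKM, Rgs9 50.3 and the synaptic membrane gene Syndig1l 18.5, from 20.6, 5.62 and 2.89, in the authors' deposited table. Drd1a and Drd2 stood at 7.87 and 12.1 RPKM in the authors' deposited table. Pde1b rose to 103 RPKM and Pde7b to 8.71 in the authors' deposited table, and phosphodiesterases numbered 3 higher and 1 lower of 18 (3 and 1 adjusted over the list alone). Among 25 genes of cyclic nucleotide synthesis and protein kinase A, 3 rose and 4 fell (3 and 4 adjusted over the list alone). Adcy5, the main adenylyl cyclase of striatum, reached 42.4 from 23.7 RPKM and Adcy9 fell 1.62-fold, from 16.3, in the authors' deposited table. The median of that list, at percentile 2.26, lay at percentile 9.10 with matching on transcript length and at 3.10 with a pseudocount of 0.1.

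Choroid plexus and ependymal markers fell in 10 of 14 members (11 adjusted over the list alone), with a median log2 fold of -1.54. Folr1 went from 13.6 to 1.36 RPKM, Aqp1 from 7.73 to 0.438 and the chloride channel gene Clic6 from 5.99 to 0.789 in the authors' deposited table. Enpp2, the lysophospholipase autotaxin of choroid plexus and oligodendrocytes, fell from 139 to 25.0 RPKM in the authors' deposited table. The calcium-binding protein genes S100a8 and S100a9 fell from 32.7 and 29.0 to 1.75 and 1.77 RPKM in the authors' deposited table. Interferon and inflammatory genes fell in 5 of 10 members (6 adjusted over the list alone), including the interferon-induced Bst2 at 4.40 against 10.1 RPKM in the authors' deposited table. Glucocorticoid-responsive genes fell in 10 of 14 (11 adjusted over the list alone), with Tsc22d3 at 35.2 against 54.0 RPKM in the authors' deposited table. Microglia markers fell in 7 of 16 and rose in 3 (7 and 3 adjusted over the list alone). The complement gene C1qb stood at 49.5 against 84.3 RPKM in the authors' deposited table.

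The median log2 fold of ribosomal protein genes was 0.52, above all 10000 random lists, and 30 of 31 rose adjusted over the list alone. Rps19 stood at 416 against 226 RPKM, Rps28 at 861 against 498 and Rpl38 at 1536 against 909 in the authors' deposited table. Respiratory chain genes rose in 9 of 29 members (14 adjusted over the list alone), among them Ndufa2 of complex I at 187 against 120 RPKM in the authors' deposited table. Their median of 0.26, at percentile 98.7, lay at percentile 92.8 with matching on transcript length. Without ribosomal protein genes, the median log2 fold of expressed genes went from 0.12 in the shortest of 10 length bins to -0.09 in the longest.

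Of the immature neuron genes, 13 rose adjusted over the list alone. The cytoskeletal genes Stmn1 and Tmsb10 reached 750 and 595 RPKM from 386 and 317 in the authors' deposited table, and Dpysl3, a growth cone protein, reached 194 from 118. Progenitor and cell cycle genes rose in 9 of 21 members (11 adjusted over the list alone). The proliferation marker Mki67 stood at 2.86 against 1.39 RPKM in the authors' deposited table. Cholesterol synthesis genes rose in 6 of 20 (8 higher and 1 lower adjusted over the list alone), including the mevalonate pathway enzymes Mvd at 29.2 against 18.8 RPKM and Fdps at 96.3 against 65.3 in the authors' deposited table. Immediate early genes rose in 9 of 24 (10 higher and 1 lower adjusted over the list alone), with the matricellular gene Cyr61 at 14.2 against 7.42 RPKM in the authors' deposited table.

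Synaptic genes that changed in KO fell more often than they rose. Among 29 presynaptic vesicle genes 9 fell and 2 rose (12 and 2 adjusted over the list alone): the vesicular glutamate transporter Slc17a7 stood at 393 against 575 RPKM and the synapsin Syn2 at 161 against 252 in the authors' deposited table. Among 33 glutamate receptor and postsynaptic genes 5 fell and 2 rose (8 and 4 adjusted over the list alone). The AMPA receptor subunit Gria2 went from 155 to 107 RPKM (adjusted p 0.00179 in the authors' deposited table). The medians of both lists, -0.12 and -0.11, lay at percentiles 3.38 and 12.5 once random lists were also matched on transcript length. Mature neuron genes fell in 4 of 20 (4 lower and 1 higher adjusted over the list alone), including the potassium channel Kcnc1 at 10.7 against 16.4 RPKM in the authors' deposited table. Voltage-gated calcium channels fell in 3 of 18 members (3 lower and 1 higher adjusted over the list alone), and their percentile of 0.510 became 3.90 with matching on length.

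Oligodendrocyte and myelin markers fell in 6 of 17 members in KO (9 adjusted over the list alone), with a median log2 fold of -0.29. The myelin protein Mal stood at 8.23 against 16.7 RPKM in the authors' deposited table. In Het the median of this list was 0.31, and 4 members rose and 1 fell (8 and 2 adjusted over the list alone). Among monoamine and neuropeptide receptors 5 of 24 rose and 8 fell (5 and 9 adjusted over the list alone), with the serotonin receptor Htr2c at 10.3 against 19.4 RPKM in the authors' deposited table. Their median of -0.20 became 0.02 over members of at least 5 RPKM. Deep-layer markers rose in 6 of 14 and fell in 1 (7 and 1 adjusted over the list alone), and hippocampal markers fell in 2 of 12 (2 adjusted over the list alone). Histone genes, with 3 measured members, had 1 lower (3 adjusted over the list alone), Hist1h2bc at 14.9 against 23.0 RPKM (adjusted p 0.00560 in the authors' deposited table), and their median of -0.60 became 0.00 with no minimum level.

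Astrocyte, interneuron, heat shock, Notch and polycomb lists had medians within the range of 95% of random lists in KO. Astrocyte markers numbered 1 higher and 1 lower of 15 (1 and 2 adjusted over the list alone), interneuron markers 1 and 2 of 18 (2 and 2 adjusted over the list alone), and heat shock genes 1 and 2 of 14 (1 and 2 adjusted over the list alone). Notch pathway genes numbered 1 higher and 1 lower of 17 (0 and 0 adjusted over the list alone, and 2 and 2 at an unadjusted p below 0.05 in the authors' deposited table). Mural cell markers rose in 2 of 11 (3 adjusted over the list alone). Of 5 sex-linked genes 1 rose and 0 fell (1 and 0 adjusted over the list alone). The one that rose was the Y-linked Eif2s3y, at 21.3 against 14.3 RPKM (adjusted p 0.0184 in the authors' deposited table). Whether the mix of sexes differed between the genotypes was not tested. In KO against WT the medians of 25 lists lay outside the range of 95% of random lists.

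Several short noncoding transcripts listed in WT were at 0 in KO. Mir6236 was listed at 0 in KO and at 1717 RPKM in WT, Gm20594 at 0 and 205, in the authors' deposited table. Mir568 was listed at 0 in KO and at 294 RPKM in WT (adjusted p 0.00386 in the authors' deposited table). Of 1062 microRNA genes in the tables, 122 were listed above 0 in WT, 115 in Het and 24 in KO. For small nucleolar RNA genes the numbers were 42, 58 and 26 of 105, and for all genes 19010, 19055 and 18899 of 23947. The drop in KO thus covered both classes of short transcripts. With pooled values a difference between libraries cannot be told apart from genotype here, so these zeros show no effect of Mir137 on other microRNAs.

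**Figure D2:**
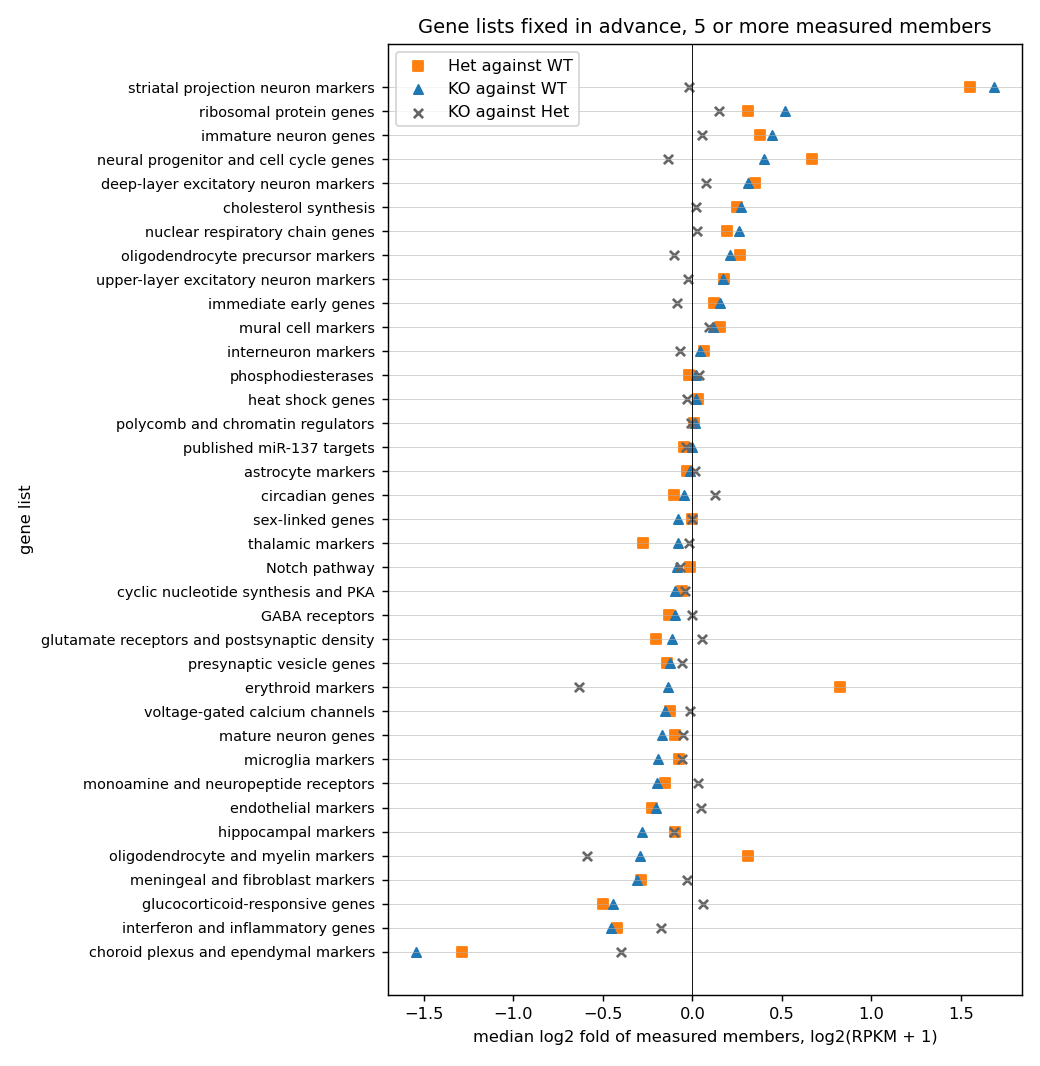
Median log2 fold of the measured members of each gene list with 5 or more measured members, on log2(RPKM + 1), for the 3 comparisons. Striatal markers stand at 1.55 and 1.68 against WT and at -0.02 between KO and Het, and choroid plexus and ependymal markers stand lowest against WT.

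Knockout and heterozygous cortex differed in fewer genes, and the group with the most calls was that of oligodendrocyte and myelin markers. These were lower in KO in 12 of 17 members (15 adjusted over the list alone), with a median log2 fold of -0.59, below all 10000 random lists. Myelin basic protein (Mbp) stood at 462 RPKM in KO and 912 in Het in the authors' deposited table. The neuropeptide neurotensin (Nts) was 5.66-fold higher in KO, at 42.8 against 7.56 RPKM in the authors' deposited table. Genes named for this comparison had an adjusted p of 0.00517, the smallest in the authors' deposited table, unless another value is given. Of 14062 genes tested, 129 were higher in KO and 134 lower.

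Pde10a stood at 27.4 RPKM in KO and 35.4 in Het in the authors' deposited table (p 0.01875, adjusted p 0.326). Of 23 striatal markers 0 were called by the authors' deposited test (0 adjusted over the list alone), 2 were higher and 2 lower at an unadjusted p below 0.05, and the median log2 fold was -0.02. Choroid plexus and ependymal markers were lower in 3 of 11 members (5 adjusted over the list alone), with Ttr at 83.8 against 283 RPKM in the authors' deposited table. Ribosomal protein genes had a median log2 fold of 0.15 at percentile 99.8, with 0 of 31 called by the authors' deposited test, 3 higher adjusted over the list alone and 5 higher at an unadjusted p below 0.05. Of the published targets, Wbp1l was higher, at 17.9 against 12.8 RPKM (adjusted p 0.0123 in the authors' deposited table), and Ptgs2 lower, at 1.75 against 3.20 RPKM in the authors' deposited table (1 higher and 1 lower of 22 adjusted over the list alone).

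The authors' deposited table listed as higher in KO the zinc finger gene Tshz2 (10.9 against 2.35 RPKM), the relaxin receptor Rxfp1 (4.78 against 0.932) and the proteoglycan Dcn (28.7 against 5.98). The stress-response gene Ndrg1 stood at 14.9 against 4.49 RPKM, the intermediate filament gene Prph at 14.2 against 5.84 and the orphan nuclear receptor Nr4a2 at 18.1 against 8.22 in the authors' deposited table. Glutamate receptor and postsynaptic genes were higher in 4 of 33 members (5 adjusted over the list alone), including the NMDA receptor subunit Grin3a at 15.8 against 8.53 RPKM in the authors' deposited table. The GABA receptor subunits Gabra2 and Gabra3 were higher as well, at 58.5 and 25.1 RPKM against 36.6 and 15.7 in the authors' deposited table. Deep-layer markers were higher in 3 of 14 and lower in 1 (4 and 1 adjusted over the list alone), with the thyroid hormone-binding gene Crym at 472 against 298 RPKM in the authors' deposited table.

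Lower in KO were the globin Hbb-bt, at 29.6 against 68.0 RPKM, and Lars2, a mitochondrial leucyl-tRNA synthetase, at 153 against 337, in the authors' deposited table. Among the largest falls, Mir6236 and Gm20594 were listed at 0 in KO and at 2136 and 157 RPKM in Het in the authors' deposited table. Mir568 was listed at 0 and 316 RPKM (adjusted p 0.00879 in the authors' deposited table). Fewer microRNA genes were listed above 0 in KO (24) than in Het (115), and fewer small nucleolar RNA genes (26 against 58). A difference between libraries cannot be told apart from genotype for these short transcripts. The myelin lipid enzyme Ugt8a stood at 15.2 against 26.8 RPKM in the authors' deposited table. The cell cycle genes Ccnb1 and Aurkb were lower, at 1.74 and 1.13 RPKM against 3.55 and 2.38 (adjusted p 0.00517 and 0.0123 in the authors' deposited table), as 2 of 21 progenitor and cell cycle genes (2 adjusted over the list alone). Presynaptic vesicle genes, 1 of 29 higher (1 and 1 adjusted over the list alone), and histone genes, 1 of 4 lower (1 adjusted over the list alone), moved from percentiles 1.59 and 0.0900 to 5.25 and 2.78 with matching on length. The medians of choroid plexus, progenitor and inflammatory lists lay within the range of 95% of random lists over members of at least 5 RPKM. The length trend seen against WT was not seen here: medians were 0.01 in both the shortest and the longest of 10 bins. The medians of 10 lists lay outside the range of 95% of random lists.

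Het and KO were then compared for the genes they changed from WT. Of 13589 genes tested in both, 817 were called in the same direction, 337 higher and 480 lower, and 9 in opposite directions. Among the largest shared rises were those of Adora2a, Penk, Ppp1r1b, Scn4b, Rgs9 and Rxrg, and among the largest shared falls those of S100a9, Ttr and Lrg1. Of the genes called in Het, 66.1% were also called in KO in the same direction. Independent lists of 1236 and 1974 calls would share 90.4 genes (37.0 higher and 53.5 lower), and unchanged genotypes simulated against the same WT values shared 5.41 on average. The libraries are pooled, so the WT controls cannot be split, and part of the excess may come from the shared controls. Simulated genes varied independently, with a spread taken from the authors' p. Shifts of whole gene groups in the WT samples are therefore left out of the simulated overlap, correlations and covariance, which may be too low. Across genes, which are not independent replicates, Pearson's r of the log2 folds was 0.670 (0.5 simulated with no effect) and Spearman's rho 0.728 (0.481). Their covariance was 0.0999 against 0.00911 simulated, a difference of 0.0908.

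**Figure D3:**
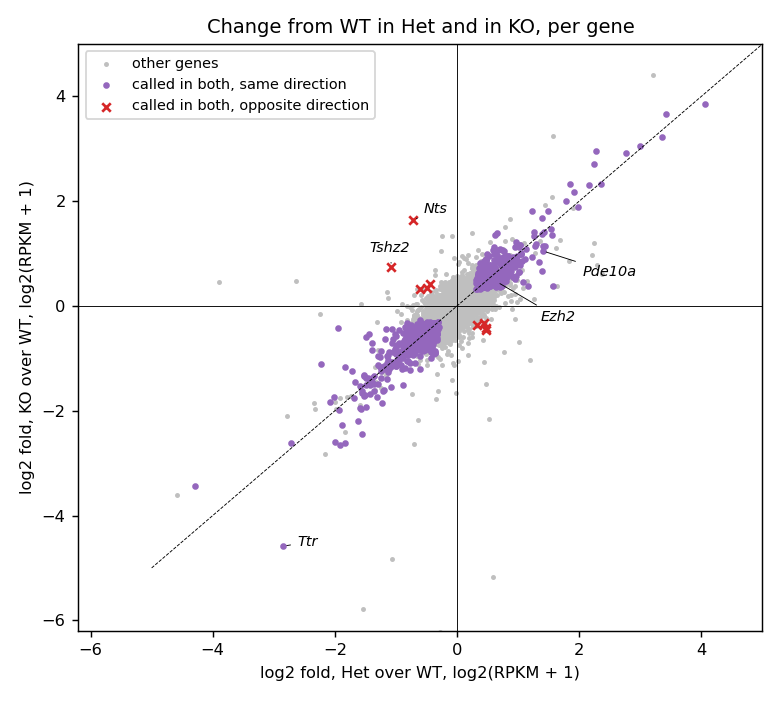
Log2 fold of each gene in Het against WT (horizontal) and in KO against WT (vertical), on log2(RPKM + 1), with genes called in both comparisons in color and a dashed line of equal change. Of 13589 genes 13571 are shown, 18 lie beyond the axes, and the 9 crosses mark genes called in opposite directions.

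Het lay between WT and KO for 1531 of 1975 genes called in KO, or 77.5%, where 49.8% were between in simulations with no effect in Het. Choosing genes by their call in KO places Het nearer to WT even if both effects are equal. The share therefore cannot show a change graded by gene dose. Nor can it show a change in Het by itself, since the simulations did not choose genes anew by their call. WT values that help a gene to be called in KO also shift its fold in Het. The simulated share and slope leave this out. Het lay beyond KO for 365 of these genes, among them Pde10a, and on the other side of WT for 79. The slope of the Het fold on the KO fold was 0.626 (0.0141 simulated). KO differed from Het by the authors' deposited test, further from WT, for 125 of these genes, including Ttr, and back toward WT for 18.

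Messages with an 8mer site for miR-137 in the 3' UTR were shifted upward against matched genes in both genotypes, and those with 7-mer sites lay within the range of 95% of matched sets against WT. In KO, 593 genes whose best site was an 8mer (AGCAATAA) had a median log2 fold of 0.03, and random sets matched on expression and 3' UTR length had a median of -0.04 with 95% of sets between -0.06 and -0.02. All 10000 sets lay below the observed value. By the authors' deposited test 63 of these genes (10.6%) rose and 40 fell (6.75%), against 6.95% and 7.80% among genes with no site. In Het the 592 genes with an 8mer had a median of 0.02 against -0.02 in matched sets, above all 10000, and 0.01 in genes with no site. By the authors' deposited test 29 of them rose in Het (4.90%) and 33 fell (5.57%), against 3.95% and 5.28% among genes with no site. Between KO and Het their median of 0.00 lay at percentile 99.8, with 14 higher and 5 lower. Sites of the 7mer-m8 class (AGCAATA) lay at percentile 96.8 in Het, 78.0 in KO and 57.5 between them, and 7mer-A1 sites (GCAATAA) at 51.8, 97.3 and 99.5. In KO the 7mer-m8 genes went the other way from the 8mer genes by the authors' deposited test, with 5.25% higher and 9.38% lower. For 7mer-A1 genes these shares were 6.94% and 7.83%, near those of genes with no site. A ranking of 7-mers took all 3' UTRs that hold AGCAATA, those with an 8mer included. Among the miR-137 7-mer and 209 others of the same base composition, the miR-137 7-mer ranked 2 from the highest in each comparison. This rank does not speak for the 7mer-m8 class alone.

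The targets that changed differ in their sites in the longest annotated 3' UTR of GENCODE M21, a mouse annotation on GRCm38. The 4995 nt 3' UTR of Pde10a-202 holds a single site, a 7mer-A1 at positions 4596 to 4602, and that of Ezh2-214 a 7mer-A1 at 208 to 214. Wbp1l-204 holds an 8mer at 2542 to 2549, and the 3' UTR of Esrra holds 8mers at 488 to 495 and 597 to 604. That of Mib1, which fell in KO, holds 7mer-m8 sites at 2715 to 2721 and 4558 to 4564. Among the other targets that fell, Grin2a holds a 7mer-A1 at 284 to 290 and a 7mer-m8 at 409 to 415, Nsf a 7mer-A1 at 1434 to 1440 and Csmd1 a 7mer-A1 at 2676 to 2682, and no site was found in the 3' UTR of Ptgs2. Genes with a 7-mer for other brain microRNAs lay within the range of 95% of matched sets in KO against WT for miR-124 (percentile 66.0), let-7 (95.2) and miR-128 (76.6), and below it for miR-9 (percentile 0.95). In Het against WT, miR-9 lay below the range as well (percentile 0.11), with miR-124 at 81.7, let-7 at 65.3 and miR-128 at 3.12. Between KO and Het, let-7 lay above the range, at percentile 99.8, the same as the miR-137 8mer, with miR-124 at 5.88, miR-9 at 66.3 and miR-128 at 91.2.

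**Figure D4:**
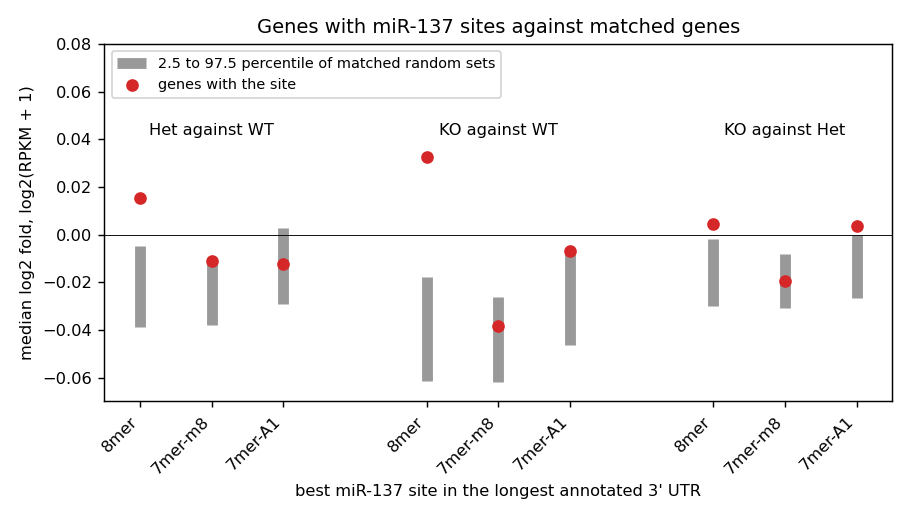
Median log2 fold, on log2(RPKM + 1), of genes whose best miR-137 site in the longest annotated 3' UTR is an 8mer, 7mer-m8 or 7mer-A1 (points), for the 3 comparisons, over the range of 95% of random sets matched on expression and 3' UTR length (bars). Genes with an 8mer lie above the range in each comparison.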

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

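The tests in this part are the authors' deposited comparisons, all chosen before the data were examined. Of the genes called against WT in both genotypes, 9 went in opposite directions, which drew attention because Het and KO share a lost copy of Mir137. In the authors' deposited table the difference between KO and Het was itself called for each, with an adjusted p of 0.00517. Genes chosen for opposite calls against the same WT must differ between KO and Het, so this adds little to the choice. The direction and the log2 difference of KO from Het follow, from the authors' RPKM. Nts, the neurotensin precursor, stood at 7.51 RPKM in Het and 42.6 in KO, on either side of WT, in the authors' deposited table, a difference of 2.35. Tshz2 stood at 2.33 RPKM in Het, 6.03 in WT and 10.8 in KO in the authors' deposited table, a difference of 1.83. Also lower in Het and higher in KO were Met, a receptor tyrosine kinase (0.92), Col6a2, a collagen (0.87), and Grin3a (0.82). Higher in Het and lower in KO were Cd109 (-0.925), the kainate receptor partner Neto1 (-0.89), the myelin lipid enzyme Ugt8a (-0.78) and the channel-related gene Ano3 (-0.69). Ano3, Cd109, Col6a2, Met and Neto1 fall outside the rule for named genes and were chosen after their values were seen.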

How the results depend on the processing

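The runs matched on transcript length, those without the genes of all lists and those without striatal, choroid plexus and ribosomal list genes were chosen after the result was seen. No paired analysis was possible because the tables hold 1 value per genotype. For the same reason leaving out libraries, a replicate block and other splits of the samples were not run, and depth sets no interval on any value.

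A stricter q of 0.01 left 779 calls in Het against WT, 1142 in KO against WT, 160 in KO against Het and 473 genes called in the same direction in Het and KO against WT, and a minimum absolute log2 fold of 0.5 left 670 in Het and 916 in KO, both by their construction. Adjusting over the 3 comparisons together raised KO against Het to 435 calls, since its p-values then share the threshold of the others, and ended 4 named calls in KO against WT (Grm4, Notch3, Pde11a and Scn1a). The share of called genes that were higher stayed between 40.7% and 50.8% in these runs. In the gene dose order, a minimum of 5 RPKM put Het between WT and KO for 80.3% of genes, and the cause was not tested. At that minimum the median of deep-layer excitatory neuron markers in Het was -0.0324 and that of monoamine and neuropeptide receptors in KO 0.0230. With no minimum the median of hypothalamic markers in Het was -0.00716 and that of histone genes in KO 0.00301. These 4 medians stood outside the percentile limits in the main run and changed sign, and the cause was not tested. Of 716 list medians under an alternative 673 kept their side of the percentile limits, 16 passed a limit they had not passed, and 23 no longer passed one. Some medians that lay within the limits in the main run also changed sign, such as that of published miR-137 targets in Het, from -0.0466 to 0.0251 with a minimum of 5 RPKM, so their sign carries no weight. Of 1576 named-gene values 1572 kept their call or its absence. The 395 values with a pseudocount of 0.1 and the 395 with recentred folds reused the authors' adjusted p. Only the sign of a fold could change there, so these values do not test the calls. The 8mer shift lay above the range of 95% of matched sets in each alternative run for each comparison. Recentring moved folds and their random lists alike, so its 120 list medians, counted among the 673, say nothing about list percentiles.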

Other observations

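Tests of gene dose, of striatal markers without a site, of the Pde10a rise, of choroid plexus markers without Ttr and of ribosomal genes between KO and Het were chosen after the result was seen. A list of 9 genes of cholinergic neurons, which use acetylcholine and lie in striatum and basal forebrain, was written before its values were seen. The transporter Slc10a4 stood at 3.10 RPKM in KO and 0.993 in WT (adjusted p 0.000987 in the authors' deposited table). The zinc finger gene Zic4 fell, from 1.64 to 0.568 RPKM (adjusted p 0.000987 in the authors' deposited table). Chat, the enzyme that makes acetylcholine, stood at 0.847 RPKM in Het and 0.0282 in WT (adjusted p 0.620 in the authors' deposited table). In WT 3 of the 9 genes reached 0.3 RPKM, and 6 were not tested by the authors in KO against WT. The genes of this list that are named were chosen after their values were seen.

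Striatal markers and Pde10a were higher in Het and KO than in WT. The 95% intervals of medians in this part come from resampling genes of pooled values. They show the spread between genes, which may vary together, and not that between animals or libraries. For the 23 markers, a response in proportion to lost Mir137 copies is argued against as the whole cause. Their median KO over Het log2 fold was -0.0214 (95% interval over genes -0.14 to 0.14), where Het over WT was 1.55. The KO over Het log2 fold of Pde10a was -0.36 (p 0.01875, adjusted p 0.326 in the authors' deposited table). That is not a call, so it does not decide the question for Pde10a. For the striatal markers, lost repression through miR-137 sites is argued against as the whole cause too. The 19 with no 8mer or 7-mer site had a median KO over WT log2 fold of 1.48 (95% interval over genes 1.14 to 2.32). Lost repression stays open for a part, as 4 of 23 markers carry an 8mer or 7mer-m8 site (random lists 0 to 5, percentile 91.8). Pde10a is not among these markers and holds a 7mer-A1 site, so this test does not speak to repression of Pde10a itself. More striatal tissue in the Het and KO samples may account for the rise of both the markers and Pde10a. In KO over WT, 8 cholinergic genes had a median ratio of 5.15 (95% interval over genes 1.204 to 11.95). Between KO and Het, though, they did not follow the striatal markers: Slc5a7, 0.486 against 1.09 RPKM, was lower in KO (adjusted p 0.00517 in the authors' deposited table). The rise of Pde10a in KO over that in Het, 0.651, lay near the low end of 21 striatal markers (0.489 to 1.77, median 1.04, 1 lower), which is weak evidence. WT cortex expressed 17 of 24 striatal list genes at 1 RPKM or more, 5 names also stand in another list, and Ppp1r1b, at 179 RPKM, was the most abundant in KO in the authors' deposited table, and any effect of genotype on these neurons, not tested apart from dissection, stays open.

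Choroid plexus genes were lower in Het and in KO than in WT. Ttr alone is argued against, since the other 13 markers had a median KO over WT log2 fold of -1.40 (95% interval over genes -1.97 to -0.60). Less choroid plexus in the Het and KO samples is a candidate explanation: 15 other choroid plexus genes, all at 0.3 RPKM or more in WT, had a median of -2.08 (-3.02 to -1.06, pseudocount 0.1), and Ttr, the most abundant named one, went from 2028 to 83.6 RPKM in the authors' deposited table. An effect of Mir137 on choroid plexus itself was not tested and stays open.

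Ribosomal protein genes were higher in Het and KO. Their KO over Het log2 fold was 0.15 (95% interval over genes 0.10 to 0.22) where that of striatal markers was -0.02. This argues only weakly against the striatal tissue difference as their whole cause. By the authors' deposited test 0 of 31 were called between KO and Het, and pooled values carry no spread between libraries. A bias by transcript length may account for part: 79 other genes of the same length and expression had a median KO over WT log2 fold of 0.25 (0.19 to 0.27) against 0.52 for the ribosomal genes. An effect of genotype on ribosomal messages was not tested apart from RNA or library quality and stays open.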
